A study of Homo sapiens with 16 samples.

How the data were processed

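Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin and inserts sequencing adapters, in frozen leiomyoma (uterine fibroid, a benign smooth muscle tumour) and myometrium (the smooth muscle wall of the uterus) of 8 patients. The labels give both tissues of a patient the same number, so the 16 libraries form 8 pairs from separate patients, and the pair was the block in every main test.

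The authors deposited 1 peak list per library, called on each sample alone. Per the series' design text, reads were trimmed with Trim Galore 0.4.4 (stringency 13), aligned to hg19 with Bowtie2 2.3.2 and filtered with SAMtools 1.7 to proper pairs of mapping quality 13 or higher. Peaks were called with MACS2 2.1.1 on whole fragments with 1 duplicate kept, per the same text. That text names no shift of reads to the transposase cut site, and a fragment-based peak is therefore placed by the fragment pileup. The deposited fold column is the authors' fold enrichment of the peak summit over the local background. The deposited columns of −log10 p and −log10 q are the authors' peak significance, and their smallest −log10 q was 1.30. The deposited score is an integer made from it and was not used. Peak start, end and summit are positions, per the file format. These values belong to single peaks and were used here to rank or filter peaks within a list. In addition, the median fold enrichment of each library was among the values tested for outliers. Read depth per library was not analysed here, so a missing peak can mean closed chromatin or too few reads.

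The files held 385685 peaks. Autosomes and X were used, and the 0.101% of peaks elsewhere were left out. Every peak ended within the GRCh37 chromosome lengths. Genes came from GENCODE 44 mapped to GRCh37, with 1 canonical transcription start for each of 20090 protein-coding symbols. PECAM1 had no protein-coding entry there, so 14 endothelial markers were used. Peak number and median width were compared over all 8 pairs. Regions, promoters and motifs were compared in the 6 pairs in which both libraries held at least 5000 peaks. Within a pair, the longer list was trimmed to the length of the shorter by −log10 p. Even so, the library with the longer original list had the higher median width in all 6 pairs.

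Consensus regions were the union of the peaks, merged at an overlap of 1 bp. The net number of pairs is the pairs with a peak in leiomyoma only minus the pairs with a peak in myometrium only. A region was called biased at a net of 5 or more of the 6 pairs. A promoter was the start ± 1 kb. For 15 gene lists, the odds ratio of a list promoter carrying a peak against all other promoters was taken per library, with 0.5 added to each cell. Differences were tested over pairs by an exact two-sided sign-flip permutation test, with Benjamini-Hochberg adjustment over lists, motifs or the 22 autosomes. Its smallest p is 0.03125 with 6 pairs and 0.0078 with 8. The lists were also set against 10000 random promoter lists matched on the number of libraries with a peak. Similarity was the Jaccard index in base pairs between libraries of different patients. Motif shares used the sequence within 100 bp of the summit and a two-sided Fisher's exact test. The 10 autosomal regions and 10 promoters with the largest net number of pairs each way were named. Ties were broken by the number of libraries over all 16, then by the other tissue, fold enrichment rank and position. Further members of the fixed lists were named as examples.

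Lists, tests, naming rule and alternatives were fixed before the data were examined. The alternatives were a −log10 q of at least 5, untrimmed lists, all 8 pairs, unpaired tests, other windows or overlaps, and leaving out each pair. Added after seeing the data were promoter presence by summits, splits by the longer list and comparisons without 1 doubted pair. Motifs were analysed 3 times. The planned test came first, then a pooled set of regions at a lower net number of pairs without the doubted pair, and then a test over pairs, with reversed motif sequences as a control of base composition. In the test over pairs a private peak is a peak of 1 tissue with no overlapping peak in the other tissue of the pair.

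The region count was tested on simulated data of 64122 regions and 6 pairs with 200 changed regions. It called 88.0% of them when a peak had a probability of 0.95 in 1 tissue and 0.05 in the other, and 10.5% at 0.7 against 0.3. Between 17 and 26 unchanged regions were also called. The simulation drew the tissues of a pair independently, so it held no likeness within patients. Other within-pair swaps of the tissue labels in the real data gave a median of 5 biased regions. A simulated list of 30 promoters shifted by 1 on the log2 scale came back at 1.15. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.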

Results

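The data were ATAC-seq peak lists of leiomyoma and matched myometrium, 8 libraries of each tissue from 8 patients. The lists held between 701 and 53133 peaks on the autosomes and X. Leiomyoma libraries held 28639 ± 20435 peaks (mean ± SD, n = 8) and myometrium libraries 19523 ± 15968 (n = 8). There were 3 lists shorter than 5000 peaks, and the 2 pairs that held them were left out of the region comparisons.

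The first comparison asked whether the tissues differed in the amount and kind of open chromatin. No direction was shared: leiomyoma held more peaks in 4 pairs and fewer in 4. The mean ratio was 1.46-fold, or 0.55 ± 2.35 on the log2 scale (SD, n = 8 pairs, exact two-sided sign-flip permutation p = 0.562). Without 1 pair, whose myometrium list was among the short ones, it was −0.06 ± 1.73. The median peak was 270 ± 60.2 bp wide in leiomyoma and 263 ± 52.0 bp in myometrium (exact permutation p = 0.648, n = 8). Peak summits lay within 1 kb of a transcription start in 43.4 ± 10.5% of leiomyoma and 50.0 ± 13.2% of myometrium peaks (n = 8 each). With lists of equal length in 6 pairs the shares were 52.9 ± 8.92% and 55.3 ± 11.5% (exact permutation p = 0.406, n = 6 pairs). The promoter share followed list length. Over the 16 libraries, which are not all independent, Pearson's r with log10 peak number was −0.52 (permutation p = 0.041). Spearman's rho was −0.80 (permutation p = 0.0005). Without the 2 libraries farthest from the median peak number r was −0.98 (permutation p = 0.0001, the smallest these permutations can give). It was the only relation across libraries computed.

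**Figure D1:**
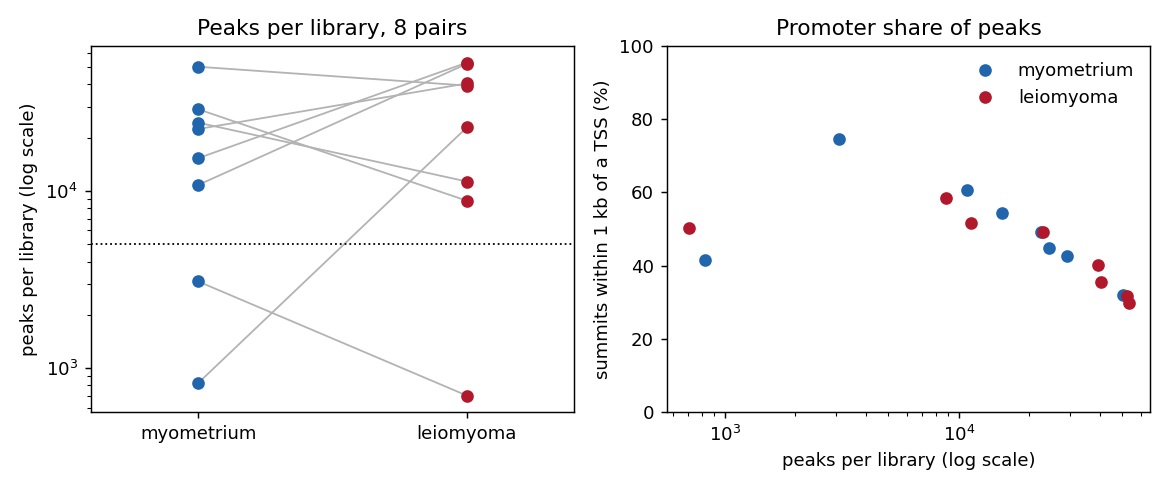
Left, peaks per library on a log scale, with lines joining the tissues of a patient and a dotted line at 5000 peaks. Right, the percent of summits within 1 kb of a transcription start (TSS) against peaks per library; lists above 5000 peaks fall on 1 declining course, and leiomyoma and myometrium libraries overlap.

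The second comparison asked which regions were open in 1 tissue across patients. The 6 pairs gave 64122 consensus regions. Of these, 3540 carried a peak in all 12 libraries and 32341 in a single library. List length was equal only within a pair and ran from 8819 to 39398 peaks between pairs. The pair whose leiomyoma library carried epithelial promoter peaks had the longest lists. Without it 36718 regions remained, against 60844 to 63473 without any other pair. Regions found in all libraries lay near a transcription start in 84.6% of cases, against 14.5% of the regions found in 1 library. With a net of at least 5 of 6 pairs, 27 regions were leiomyoma-biased and 35 myometrium-biased. Of these, 4 of the 27 and 8 of the 35 lay within 1 kb of a transcription start, against 28.5% of all consensus regions. The total of 62 was reached by 3 of the 32 ways of swapping tissue labels within pairs, the real labels included, so it was not beyond chance. Without the pair whose leiomyoma library carried epithelial promoter peaks, the counts were 282 and 168 at a net of 4 of 5 pairs.

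Counts of libraries for single regions and promoters are of the 6 pairs with trimmed lists unless stated. On these, 2 regions had a peak in all 6 leiomyoma and no myometrium libraries. In the untrimmed lists of all 8 pairs, 7 leiomyoma libraries and 1 myometrium library had a peak in the first, and 6 and 2 in the second. The first, at chromosome 10, 5508238 to 5509452 (hg19), was intergenic, 32.1 kb from the start of CALML5. The second, at chromosome 21, 40361655 to 40362509, lay outside protein-coding genes and overlapped the noncoding gene LINC02940. A region at chromosome 17, 77680571 to 77681478, overlapping MIR4739 and LINC02078, was open in 6 leiomyoma libraries and 1 myometrium library. The same counts held at chromosome 19, 11650517 to 11650945, inside CNN1 and 0.851 kb from its start, while the CNN1 promoter as a whole had a peak in 5 leiomyoma and 4 myometrium libraries. CNN1 encodes calponin, an actin-binding protein of smooth muscle. They also held in an intron of ANO1, which encodes a calcium-activated chloride channel, at chromosome 11, 69952085 to 69952881. The other leiomyoma regions of the 10 lay in an intron of CCDC171, at the MARCHF1 promoter, and between genes nearest to SPATA31C2, SIK1 and ALG10, each at 6 libraries against 1.

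Towards myometrium, the first region lay in an intron of PLA2G6, a phospholipase gene, at chromosome 22, 38572222 to 38572524. It was open in 5 myometrium and no leiomyoma libraries. The same counts held in introns of ABR, VEPH1, SNX9 and VDAC2. They held also at the promoter of AL590560.1 and in an intergenic region nearest to ADAMTS9. An intron of ANK2, the gene of the membrane adaptor ankyrin-B, was open at chromosome 4, 114221591 to 114221996, in 6 myometrium libraries and 1 leiomyoma library. The remaining regions lay in an intron of SLC35F6 and nearest to ADIPOR2, at 6 libraries against 1.

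At promoters, 1 gene was leiomyoma-biased and 3 were myometrium-biased at a net of 5 pairs, out of 20090. MARCHF1, a membrane ubiquitin ligase gene, carried a promoter peak in 6 of 6 leiomyoma and 1 of 6 myometrium libraries. The other leading leiomyoma promoters had 6 libraries against 2. They were GALNT13, TRMT10C, RPL22L1, MAP3K10, DECR2, ATG14, MCOLN1, and C22orf23 and POLR2F, neighbours that share a promoter. A −log10 q of at least 5 turned ATG14 towards myometrium. CAVIN2, the gene of a coat protein of caveolae, had 1 leiomyoma and 6 myometrium libraries. FGL2, a fibrinogen-like protein gene, had 0 and 5, as had AL590560.1. EPAS1, the gene of hypoxia-inducible factor 2-alpha, FAM107A, a glucocorticoid-induced gene, and RNF125 had 1 and 5. FOXC1, APOLD1, ENPP4 and TEX2 had 2 and 6. In the untrimmed lists of all 8 pairs the contrasts of these myometrium promoters were smaller, with 4 and 6 for CAVIN2, 3 and 5 for FGL2, 2 and 6 for AL590560.1, 4 and 6 for FAM107A, and 5 and 6 for EPAS1 and RNF125. A net of at least 4 pairs was reached by 20 promoters towards leiomyoma and 19 towards myometrium. A single gene cannot pass an adjusted test with 6 pairs.

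Of 15 gene lists, none passed adjustment over the lists, and 2 reached the smallest p that 6 pairs allow. Promoters of HOX genes, which set position along the body and the reproductive tract, carried peaks more often in leiomyoma in 6 of 6 pairs. The shares were 18.1 ± 11.5% and 11.0 ± 10.4% (SD, n = 6 each). The difference was 1.06 ± 0.66 on the log2 odds scale (exact permutation p = 0.03125, adjusted p = 0.234). Of 35 members, 12 had a net towards leiomyoma, 1 towards myometrium and 22 neither. HOXA10 had 4 leiomyoma and 1 myometrium libraries, HOXA13 had 3 and 1, HOXD8 5 and 3, and HOXA11 5 and 4. Counting peak summits turned HOXD8, and a −log10 q of at least 5 turned HOXA13, towards myometrium. Housekeeping promoters, a control for depth, were lower in leiomyoma in 6 of 6 pairs, at 75.6 ± 17.1% and 83.3 ± 11.8%. That difference was −0.77 ± 0.62 (exact permutation p = 0.03125, adjusted p = 0.234, n = 6). It was 0.13 with untrimmed lists, while the HOX difference was 1.01 ± 1.1 and positive in 4 of 6 pairs (exact permutation p = 0.125). The HOX difference was 0.67 ± 1.13 with a −log10 q of at least 5, positive in 5 of 6 pairs (exact permutation p = 0.219). It was 0.64 ± 1.23 over gene bodies, positive in 4 of 6 (exact permutation p = 0.3125), and 0.79 ± 0.56 within 500 bp of the start, positive in 5 of 6 (exact permutation p = 0.0625).

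Contractile smooth muscle genes had promoter peaks at 75.8 ± 14.3% in leiomyoma and 67.5 ± 21.9% in myometrium, a difference of 0.29 ± 1.74 (exact permutation p = 0.781, n = 6). It was positive in 5 of 6 pairs. Without the pair with epithelial promoter peaks it was 0.99, positive in 5 of 5 (exact permutation p = 0.0625, the smallest 5 pairs allow). That pair was the only one with a negative difference, so the count and the p were fixed by leaving it out. In the 3 pairs with the longer myometrium list the difference was −0.41 ± 2.46, and the pair with epithelial promoter peaks is among them. That pair had 17 leiomyoma and 20 myometrium promoters with a peak, and the others 13 and 10, and 11 and 10. Of 20 members, 8 had a net towards leiomyoma and 2 towards myometrium. MYH11, the smooth muscle myosin heavy chain gene, had 5 leiomyoma and 2 myometrium libraries, TPM2 5 and 3, and KCNMB1 4 and 2.

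Endothelial promoters carried peaks at 5.95 ± 8.35% in leiomyoma and 17.9 ± 17.3% in myometrium, a difference of −1.27 ± 1.38 (exact permutation p = 0.125, n = 6). Of 14 members, 6 had a net towards myometrium and none towards leiomyoma. ERG, CLDN5 and EMCN had 0 and 2 libraries (EMCN turned towards leiomyoma with untrimmed lists), and FLT1, a receptor of vascular growth factor, 1 and 3. The summed net of the list lay at percentile 0.005 of the random lists, which drew promoters singly. The log2 odds difference was positive in 2 of 6 pairs. It was −2.33 ± 0.35 in the 3 pairs with the longer leiomyoma list and −0.22 ± 1.14 in the 3 others. The first 3 rest on few peaks, with 0 leiomyoma and 2 myometrium promoters of 14, 0 and 1, and 1 and 5. In the others the counts were 1 and 1, 0 and 0, and 3 and 6. Leukocyte markers differed by −0.16 ± 1.05, pericyte markers by 0.73 ± 1.20 and fibroblast markers by 0.37 ± 0.71 (n = 6 pairs each). Epithelial markers differed by 0.88 ± 2.88, and by −0.24 without the pair whose leiomyoma library carried 10 of the 12 promoters.

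The other lists differed by less than their SD over 6 pairs. The values were −0.47 ± 0.85 for AP-1 and immediate early factors and 0.26 ± 0.46 for Müllerian and mesenchymal transcription factors. They were −0.20 ± 0.54 for extracellular matrix, 0.16 ± 0.69 for steroid hormone receptors and targets, and 0.09 ± 0.50 for leiomyoma-associated genes. TGF-beta and WNT genes differed by 0.06 ± 0.69, and liver and neuron genes, a background list, by 0.34 ± 1.54. With a −log10 q of at least 5 the steroid list was at −0.62, and with untrimmed lists extracellular matrix was at 0.25. Members with a net towards leiomyoma and towards myometrium numbered 5 and 11 of 22 for extracellular matrix, 7 and 10 of 31 for TGF-beta and WNT, and 1 and 6 of 21 for AP-1 factors. They numbered 6 and 2 of 29 for Müllerian and mesenchymal factors, 3 and 2 of 17 for the steroid list and 4 and 3 of 20 for leiomyoma-associated genes. Among members, WNT2 had 3 leiomyoma libraries and no myometrium library, and FZD7, a WNT receptor gene, had 4 and 6. HAND2 had 5 and 2, and HSD17B6 4 and 1. NR3C1, the glucocorticoid receptor gene, and JUNB had 4 and 6. Such leans towards myometrium were also seen in the depth control, where housekeeping members numbered 2 and 11 of 26. Among matched random lists, the summed net lay at percentile 12.8 for AP-1 factors, 19.5 for extracellular matrix and 52.1 for TGF-beta and WNT. These member counts are therefore not shown to be particular to the lists.

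**Figure D2:**
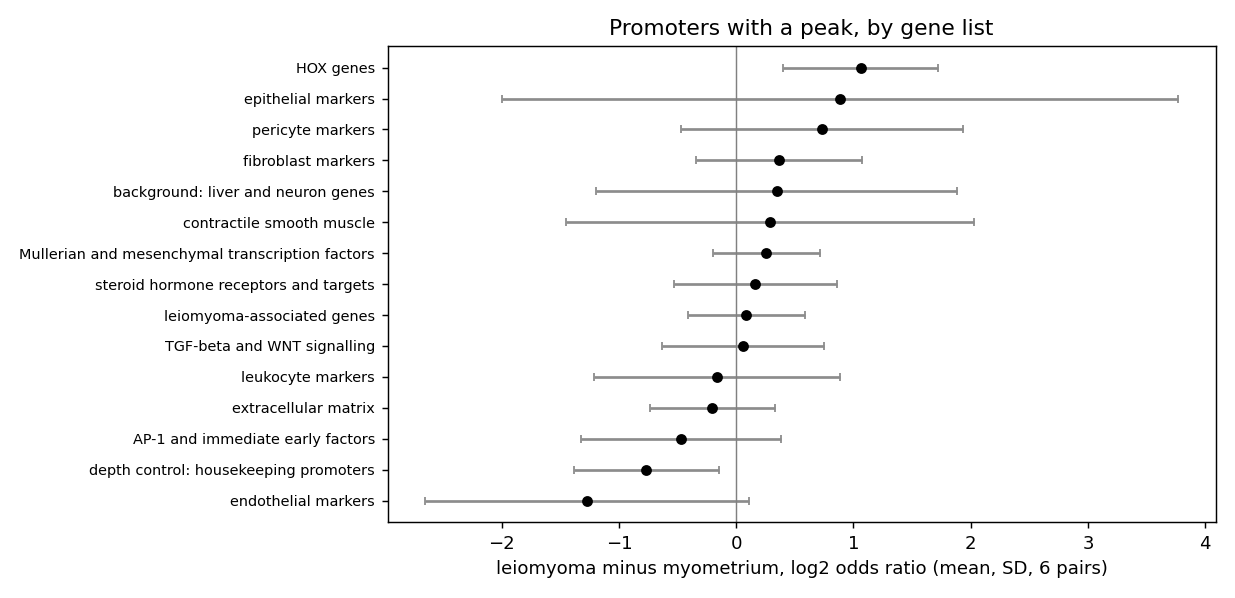
Mean difference between leiomyoma and myometrium in the log2 odds ratio of a list's promoters carrying a peak, with bars of 1 SD over 6 pairs. HOX genes lie highest at 1.06 and endothelial markers lowest at −1.27; the SD bars of HOX and housekeeping promoters stay clear of 0.

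The motif comparison asked which transcription factor sites marked the regions of each tissue. In the planned test on 27 and 35 biased regions, none of 10 motifs passed adjustment, and none had an unadjusted p under 0.05 within 100 bp of the summit. The TEAD motif was in 1 and 8 regions (Fisher's exact p = 0.0649), the HOX motif in 9 and 5 (Fisher's exact p = 0.124) and the CArG box in 4 and 1 (Fisher's exact p = 0.158). The hormone response element, defined below, was in 0 and 1 regions, both within 100 bp and within 50 bp, so the planned test showed no difference for it. Within 50 bp, GATA was in 0 and 6 regions (Fisher's exact p = 0.0312, adjusted p = 0.312), TEAD in 0 and 5, the HOX motif in 4 and 2 and CArG in 2 and 1. A pooled set of 1203 leiomyoma and 823 myometrium regions, at a net of 3 of 5 pairs without the pair with epithelial promoter peaks, was examined next, after the data were seen. There the HOX motif was in 448 and 140 of these regions, CArG in 6.90% and 0.729%, the hormone response element in 0.499% and 5.95% and TEAD in 6.98% and 13.0%, and regions are not independent replicates. A motif test with the pairs as replicates, chosen after both, used the private peaks of each tissue, 40963 in leiomyoma and 40489 in myometrium. Without the pair with epithelial promoter peaks these numbered 24335 and 23810.

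The shared response element of the progesterone, glucocorticoid and androgen receptors (GNACANNNTGTNC) was rarer in leiomyoma-private peaks in 6 of 6 pairs. It lay near 0.648 ± 0.150% of leiomyoma and 1.78 ± 0.529% of myometrium private summits (SD, n = 6), 2.75-fold more in myometrium. The exact permutation p was 0.03125, the smallest possible, and the adjusted p was 0.312. Over all 8 pairs the difference was −0.85 ± 0.73 percentage points, lower in leiomyoma in 6 (exact permutation p = 0.03125). Among consensus regions, 583 held the element, 354 with a net towards myometrium and 141 towards leiomyoma. At a net of at least 3 pairs it was in 58 of 1061 myometrium regions and 2 of 999 leiomyoma regions.

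The HOX motif (TTTATNR) lay near 24.1 ± 7.16% of leiomyoma and 17.9 ± 6.49% of myometrium private summits, higher in leiomyoma in 5 of 6 pairs (exact permutation p = 0.281). The CArG box (CCWWWWWWGG), bound by serum response factor at contractile genes, was at 3.36 ± 1.85% and 1.79 ± 1.03% (exact permutation p = 0.219, n = 6). Without the pair with epithelial promoter peaks both were higher in leiomyoma in 5 of 5 pairs, by 10.8 ± 5.90 and 2.44 ± 2.1 percentage points (exact permutation p = 0.0625 each). That pair was the only one lower in leiomyoma for both motifs, so the count and the p were fixed by leaving it out. With untrimmed lists the differences were 3.74 and 0.59 points. In the 3 pairs with the longer myometrium list that of CArG was −0.71, and the pair with epithelial promoter peaks is among them. In that pair CArG was at 0.776% in leiomyoma and 3.59% in myometrium. In the others it was at 2.62% and 2.15%, and at 2.17% and 1.97%. TEAD differed by −1.70 ± 2.42 points and AP-1 by −1.26 ± 9.87, with AP-1 higher in leiomyoma in 4 of 6 pairs. GATA, CTCF, RUNX, the estrogen response element and NF1 differed by −0.38 ± 5.79, −0.36 ± 1.14, −0.21 ± 0.67, 0.06 ± 0.12 and −0.01 ± 0.03 points. Without the pair with epithelial promoter peaks AP-1 turned to 2.04 ± 6.31, GATA to 0.94 ± 5.37 and RUNX to 0.01 ± 0.48, and TEAD was at −1.96 ± 2.61. With untrimmed lists the estrogen response element was at 0.173% and 0.0915%, higher in leiomyoma in 6 of 6 pairs (exact permutation p = 0.03125, adjusted p = 0.156), the same p values as those of the progesterone and glucocorticoid element there.

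**Figure D3:**
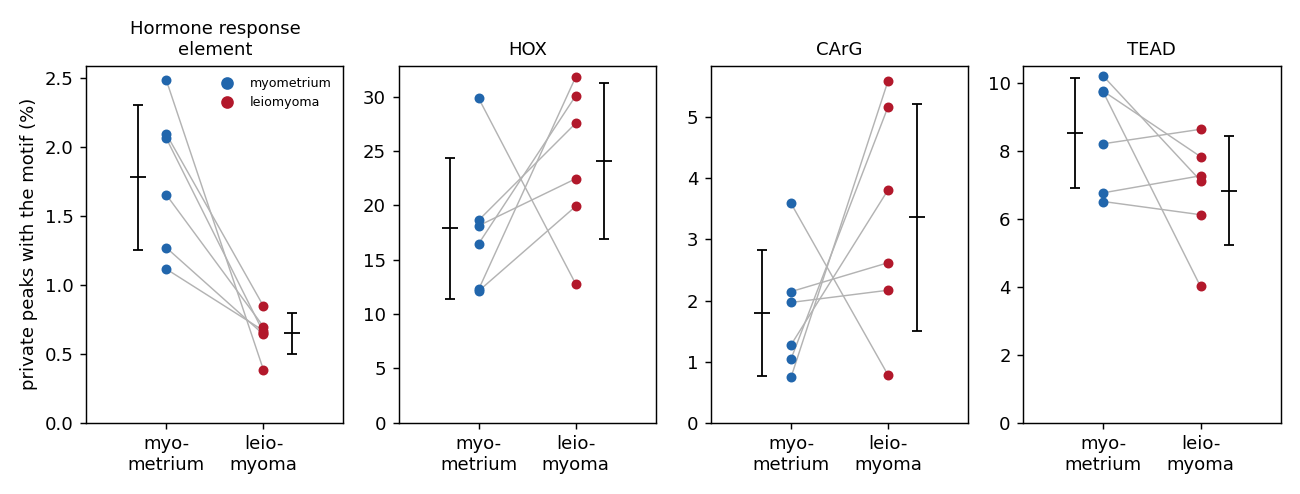
Percent of private peak summits with a motif within 100 bp, per library, with lines joining the tissues of a patient and black bars for mean ± SD (n = 6 pairs; axes start at 0 and differ between panels). The hormone response element lies lower in leiomyoma (mean 0.648%) than in myometrium (1.78%) in each of the 6 pairs, while 1 pair runs against the others for HOX and CArG.

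**Figure D4:**
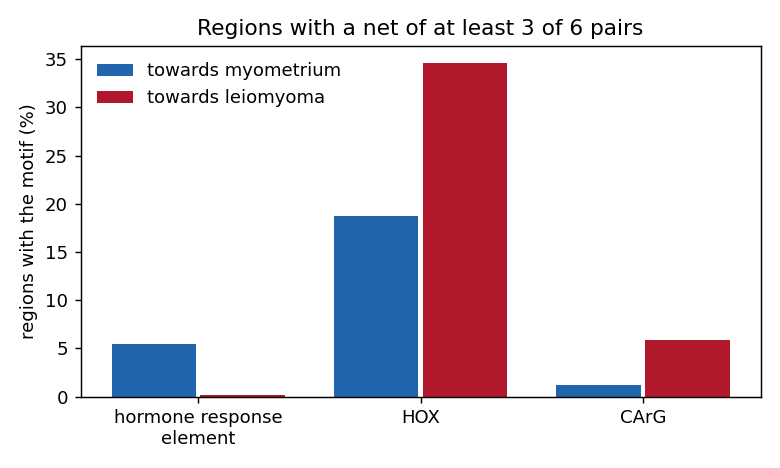
Percent of consensus regions holding a motif, among regions with a net of at least 3 of 6 pairs towards myometrium (1061) or leiomyoma (999). The response element is at 5.47% and 0.20%, the HOX motif at 18.8% and 34.6%, and the CArG box at 1.23% and 5.91%. Regions are not independent replicates. At any net, 5407 HOX regions lean towards myometrium and 4868 towards leiomyoma, and 525 and 490 CArG regions. Without the pair with epithelial promoter peaks these are 2295 and 3878 for HOX, and 180 and 490 for CArG.

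Similarity between libraries did not pass a test for a same-tissue excess. The mean among leiomyomas was slightly below that across tissues, a gap within the spread that was not tested. Between different patients, the Jaccard index was 0.296 ± 0.143 among leiomyomas (15 pairs of libraries), 0.367 ± 0.0774 among myometria (15) and 0.311 ± 0.0866 across tissues (30). The same-tissue excess of 0.020 had an exact permutation p of 0.25 over 32 label swaps, n = 6 pairs. For the share of peaks on each autosome, none of 22 passed adjustment, which 6 pairs could hardly allow. Chromosome 9 held 4.56% of leiomyoma and 4.33% of myometrium peaks, higher in leiomyoma in 6 of 6 pairs by 0.224 ± 0.156 points. Chromosome 3 held 5.98% and 6.20%, lower in leiomyoma in 6 of 6 pairs by a difference of −0.212 ± 0.116 points. Both had an exact permutation p of 0.03125 and an adjusted p of 0.344, n = 6.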

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

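Tests chosen after the result was seen are those on list length and the doubted library for HOX promoters, on a swap and on a library wholly of another type, and on the regional counts. The tests on source lists, GC content, peak summits and promoter counts were set before their own values were seen, though the summit setting was added after seeing the data. Of 58 groups of libraries tested for an outlying value, 5 had one, where about 1 in 20 is expected by chance.

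Epithelial promoters stood apart in 1 leiomyoma library. Its log2 odds ratio was 1.25 against −3.15 for the next library, a gap of 0.741 of the range. It carried 10 of 12 promoters, among them EPCAM, CDH1, KRT8, KRT18 and GRHL2, where the other 5 leiomyoma libraries had a median of 0. A library wholly of another cell type stays open: 85.0% of the contractile promoters carried peaks in it, but so did 63.9% of all promoters, above the 60% set as the bar. Epithelial cells in the sample stay open too, as 5 of 12 further epithelial genes carried a peak, short of the 8 set beforehand. Of those 12 genes 0 carried a peak in the myometrium of the pair, and at most 1 in any other leiomyoma library. Of 7 Müllerian epithelial genes 4 carried a peak in this library, the highest share of 6 epithelial origins. The myometrium of the same pair had 2 of those 7. The share of 57.1% was below the 63.9% of all promoters with a peak in the leiomyoma library. PAX8 and KRT7 of that list had been seen without a peak there when it was chosen, PAX2 is in another list too, and HOXB13 of the prostate list is a HOX gene. A swap of the tissues within the pair could not be settled: of regions biased in the other pairs, only 6.78% of the leiomyoma-biased but 53.3% of the myometrium-biased ones that differed went the same way. In that pair the HOX motif, the CArG box and the contractile promoters (17 of 20 in leiomyoma, 20 in myometrium) ran against the 5 other pairs, while the hormone response element and HOX promoters ran with them.

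HOX promoters were higher in leiomyoma in 6 of 6 pairs, and in 4 of 6 with untrimmed lists. The sign did not turn with list length: the smaller mean of the pairs with the longer leiomyoma and the longer myometrium list was 0.96. Housekeeping promoters, the depth control, also kept 1 sign in this split, at −0.59 and −0.95. The split therefore cannot tell an effect of list length or trimming from a tissue difference. For GC content, the list lay at percentile 99.9 of 10000 promoter lists matched on it and on the number of libraries with a peak. GC matching was dropped where too few promoters shared both values. The random lists drew promoters singly, whereas HOX genes lie in clusters where neighbours can share peaks. The percentile may therefore be too extreme, and it argues against GC content only with that limit. Wide peaks left 0.87 ± 0.52 with summits alone, and leaving out the library with epithelial peaks left 1.20 ± 0.63. A difference in regional identity or in the cells sampled may remain, as an untested hypothesis, since the list did not pass adjustment and fell to 0.67 with the stricter peaks.

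Chance cannot be excluded for the number of biased regions: 3 of 32 label swaps gave at least the real 62 regions, the highest other giving 162, by swapping only the pair with the epithelial peaks. For promoters 2 of 32 gave at least the real 4. Without the doubted pair only 16 swaps exist, too few for a share under 0.05. The real labels gave 450 regions there, ranked 1, and the highest other 276. This rank did not hold with untrimmed lists of the same pairs. There 5 of 16 swaps gave at least the real 738 regions, the highest other giving 5215.

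Other values stood apart as follows, without explanation, and those of TGF-beta and WNT promoters and of the AP-1 and HOX motifs lie in the pair with the epithelial peaks. TGF-beta and WNT promoters reached a log2 odds ratio of 2.20 in 1 leiomyoma library against 0.61 for the next, a gap of 0.662 of the range. The AP-1 motif was near 25.4% of private summits in 1 myometrium library against 14.3%, a gap of 0.703. The HOX motif was near 29.8% in 1 myometrium library against 18.6%, a gap of 0.633. The estrogen response element was near 0.347% in 1 leiomyoma library against 0.170%, a gap of 0.663. Outside the comparisons, the lists held 8.125 mitochondrial peaks per library on average (range 6 to 12), 8.125 in each tissue.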

How the results depend on the processing

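Peak number, width, similarity and promoter share stayed on their side of the threshold in every alternative run, and no list or autosome passed adjustment in any. This says little where few pairs limit the p: with 5 pairs none can be under 0.0625, and lists and autosomes could hardly pass with 6. The sign of the promoter share turned with all 8 pairs, at 1.21 points. The counts of biased regions moved most. Leiomyoma-biased and myometrium-biased regions numbered 0 and 0 with all 8 pairs (a net of 7), 10 and 7 with a −log10 q of at least 5, 8 and 14 when 50% of a region had to be covered, and 227 and 239 at a net of 4. Leaving out each pair, with a net of 4 of 5, gave 39 to 282 and 60 to 169, a change of pairs and threshold together. The total was 450 without the doubted pair and as low as 99 without another. Without the doubted pair and with untrimmed lists, an addition, they were 648 and 90. The cause of these changes was not tested. Untrimmed lists gave 29 and 29, and 500 bp windows 30 and 36. With untrimmed lists, however, 13 of 32 label swaps gave at least as many regions as the real labels, which are counted among them. That number was 9 of 32 with 50% coverage, and 3 of 32 with 500 bp windows and in the main setting.

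Without the pair block the counts stayed 27 and 35 by construction, and 21 of 100 regroupings of all libraries gave as many, the highest 844. The unpaired exact permutation p was 0.594 for peak number, 0.80 for width and 0.684 for promoter share. The block changed no call. Leaving out each of 8 pairs, an addition, gave a log2 peak ratio of −0.06 to 0.93 and a width difference of −0.286 to 18.1 bp. Leaving out each of 6 gave a same-tissue excess in Jaccard index of 0.00511 to 0.0339 and a promoter share difference of −3.92 to −0.684 points. At a net of 3 of 5 pairs without the doubted pair, 4 motifs passed adjustment against 0 in the planned test, on 1203 and 823 regions.

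The 20 named regions kept their direction with untrimmed lists, a −log10 q of at least 5 and 50% coverage. Leaving out a pair or adding the 2 others could not have turned them, and 500 bp windows were not run for single regions. Read depth was not analysed. There were 3 libraries with under 5000 peaks, and a promoter without a peak in a short list is not shown to be closed.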

Other observations

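Regions with the hormone response element leaned towards myometrium. At a net of at least 4 pairs there were 21 towards myometrium and 0 towards leiomyoma. The following were chosen after their values were seen, with counts from trimmed lists of 6 pairs. The element GAACATTCTGTGC lay at chromosome 16, 69287824 to 69287836 (hg19), in an intron of SNTB2, in a region open in 6 myometrium libraries and 1 leiomyoma library. GAACATCATGTCC lay at chromosome 3, 58563288 to 58563300, at the start of FAM107A, open in 5 and 1. GAACAGGATGTTC lay at chromosome 12, 92424614 to 92424626, between genes, 115 kb from the start of BTG1, a growth-arrest gene, open in 5 and 1. GGACAGCGTGTAC lay at chromosome 3, 105511368 to 105511380, in an intron of CBLB, open in 6 and 2. GGACAATTTGTTC lay at chromosome 8, 27797578 to 27797590, in an intron of SCARA5, open in 4 and 0.

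Of the tests below, those on list length and promoters for the HOX motif were set before their own results but after the pooled motif shares had been seen. Those on the response element and on endothelial genes were set after, as was the reading of reversed sequences against their spread. For the response element, base composition is argued against: the reversed sequence, which holds the same bases, differed by 0.643 ± 10.5% of the motif's difference. The doubted library (−1.27 ± 0.55 without its pair) and the share of promoters (−1.71 ± 0.85 away from them) are argued against too. The sign did not turn with list length. The pairs with the longer leiomyoma and the longer myometrium list both had a negative mean, the one nearer 0 being −0.78 ± 0.42 points (n = 3). Housekeeping promoters, the depth control, also kept their sign in this split. The split therefore cannot tell an effect of list length or trimming from a tissue difference. A lower activity of a receptor of this class in leiomyoma may account for the motif difference. So may a different local hormone exposure or cell mix of the samples. Hormone exposure of the whole patient is shared by both tissues of a pair. None of these explanations was tested, and the motif did not pass adjustment over 10.

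For the HOX motif base composition stays open. The reversed sequence differed by −7.02 ± 115% of the motif difference, a spread wider than the difference itself. Without the doubted pair it differed by 1.80 ± 5.09 points, in the direction of the motif. List length and promoters stay open too. The mean was 3.42 ± 18.7 points in the pairs with the longer myometrium list, and 7.51 ± 13.1 away from promoters, with 1 pair against the others.

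A lower share of endothelial cells in the leiomyoma samples was tested as a hypothesis on 16 further endothelial genes chosen before the test. CLEC14A among them had already been seen to lean towards myometrium, and GATA2 is in another list too. Their mean difference was −1.37 ± 1.64 on the log2 odds scale, lower in 4 of 6 pairs (exact permutation p = 0.125), within its spread, so this could not be settled.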
